A study of Mus musculus with 14 samples.

How the data were processed

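RNA was measured by sequencing in 14 mouse libraries on the C57BL/6 background. Per the labels, 8 libraries came from sorted luminal prostate epithelial cells and 6 from whole prostate tissue. The sorted cells carried a tamoxifen-inducible Cre recombinase under the keratin 8 (CK8) or keratin 5 (CK5) promoter and a Cre-activated yellow fluorescent reporter, with or without a conditional allele of Ar, the androgen receptor gene on the X chromosome. Pups received 0.1 mg of tamoxifen on postnatal day 2. Prostates were taken at 4 weeks, the lobes of 1 to 5 males of a litter were combined, and reporter-positive cells with low or no CD49f were sorted. Each sorted library is thus a pool from a single litter. Whether different libraries came from different litters is not given in the sources used here, and the tests treat them as independent. The bulk libraries, labelled WT for wild type, came from pools of 2 to 3 prostates of untreated males aged 3 weeks. Sorted cells were lysed directly and amplified with a low-input SMART-Seq kit. The labels describe a separate RNA isolation for bulk tissue, and name poly-A selection and an Illumina TruSeq kit. Sorting, genotype, age, tamoxifen, RNA input and amplification thus differ together between sorted and bulk libraries.

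The deposited table holds log2-scale normalized expression values, with 1 column per library and 1 row per gene symbol. Per the submitters' processing notes, bcl2fastq 2.17, STAR 2.5.2b, featureCounts 1.5.0-p3 and DESeq2 were used with the mm10 build. Per the labels, reads of a sample came from a pair of Illumina HiSeq models. The annotation, the strand setting, any filter and the transform behind the log values are not given in the sources used here. The values run from -2.94 to 18.10, and 27.0% lie below 0. Raised to a power of 2, they sum to 14.3e6 to 18.3e6 per library. The lowest value a gene takes differs between genes, as in a transform that shrinks low genes towards their mean. Log2 differences of weakly expressed genes are therefore understated or depend on the transform, and a value below 0 stands for little or no signal. The file holds no counts, so the sequencing depth of each library is unknown and no counting interval is given. In place of depth, the number of genes at or above a floor is given per library.

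The table has 20528 rows. 2 symbols (March1 and March2) occur more than once, and their 4 rows were left out, which leaves 20524. All columns could be assigned to a sample by the identifier in its title, with 0 columns left over. The table has 0 rows for transcripts of the mitochondrial genome. Gene identifiers and positions are from GENCODE M21 on GRCm38, the assembly that mm10 names, in which 19157 of the 20528 symbols were found. Reads of paralogs and overlapping genes could not be separated from this table.

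Tests used limma 3.58.1 in R 4.3.3 on the values as deposited, with no pseudocount, empirical Bayes moderation with a mean-variance trend, and Benjamini-Hochberg adjustment over all tested genes at 0.05. A gene was tested if its value reached log2 of 11 (3.46) in at least 2 libraries of the fit. All SE, p and adjusted p values of single genes come from these limma fits unless another test is named. The 8 sorted libraries were fitted together in every comparison among sorted cells. The main comparison of AR-deleted with control cells has lineage as an additive term, and that of CK5-traced with CK8-traced cells has genotype as one. Comparisons within a lineage or a genotype, and the interaction, used 1 mean per group. The CK8-traced control group has 1 library, which is assumed to vary like the other groups. Bulk tissue was compared with control luminal cells in a fit of all 14 libraries in 3 groups. A test on counts with edgeR or DESeq2 was not run, since the values are not counts. The target gene was tested by an exact permutation test over the 56 ways to choose 5 of 8 libraries.

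A set of 34 gene lists (pathways, prostate identities and markers of other cell types) was tested with limma's camera at a preset inter-gene correlation of 0.01. Each was also tested with camera at an estimated correlation and with fry, all with Benjamini-Hochberg adjustment over lists with at least 3 tested genes. Of the 580 list members, 27 were absent by name, and 9 of these were found under an older symbol. Camera compares a list with all other genes, whereas fry asks whether the members move 1 way on balance. No camera call in any of the 8 comparisons held with an estimated correlation (smallest adjusted p = 0.0757). Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Ar in every library. It names, past the threshold, up to 12 rising and 12 falling genes for the main AR comparison, and up to 6 and 6 for the others. These have no overlap between the groups and a linear mean of at least 50 in the higher group. Where fewer than 3 genes passed in a direction, the 3 with the smallest p and that mean are named and said not to pass. Up to 4 members with the smallest p are taken per list. Predicted genes were only counted. Genes named outside the rule are marked as chosen after their values were seen.

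The fits were tested on simulated data with 200 genes changed by known sizes on 13400 genes. In the main AR comparison 0% of genes changed by 1 log2 unit were recovered, 30% at 2, 50% at 3 and 58% at 4 units, with 5 false calls among 74. In the CK8-traced AR comparison the shares were 0%, 0%, 14% and 20%. In the CK5-traced AR comparison they were 0%, 8%, 34% and 38%. In the lineage comparison they were 6%, 36%, 62% and 58%. In the comparison with bulk tissue, run on 14959 genes, they were 18%, 58%, 72% and 86%. A simulated shift of 1 list by 1 log2 unit was called by camera in each of these 5 comparisons, with 1 of the 30 other lists also called in the main AR comparison and 0 in the other 4 comparisons. With an estimated correlation it was called in 4 (adjusted p = 0.00415 main AR, 0.0330 CK5-traced AR, 0.00177 lineage, 2.16e-05 bulk tissue) and not in the CK8-traced AR comparison (0.0632). Genes were simulated independently of each other, so these calls do not show how often camera errs on lists whose members vary together. In the measured data of the main AR comparison the estimated correlation was 0.398 for secretory and 0.488 for immediate early genes.

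The alternatives were pseudocounts of 0.1 and 5 added on the linear scale, no filter or a filter at 50, quantile normalization, median centring, limma without the trend, with robust moderation or with sample weights, other models and samples in the fit, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9.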

Results

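Gene expression was measured in luminal epithelial cells of the developing mouse prostate in which Ar had been deleted shortly after birth. Cells descended from keratin 8-expressing (CK8-traced) or keratin 5-expressing (CK5-traced) cells were sorted by their lineage label. The series holds 1 CK8-traced control library, 3 CK8-traced AR-deleted, 2 CK5-traced control and 2 CK5-traced AR-deleted libraries, with 6 libraries of bulk prostate for reference. Values are the deposited log2 normalized values, and the sequencing depth is unknown. Sorted libraries had 11457 to 12484 genes at or above the floor, and bulk libraries 14100 to 14272. The lowest numbers were those of CK5-traced control replicate 2 (11457), the CK8-traced control (11532) and CK8-traced AR-deleted replicate 2 (11746). Replicates correlated across genes at r of 0.978 to 0.990 in bulk tissue, 0.940 in CK5-traced AR-deleted cells, 0.874 to 0.887 in CK8-traced AR-deleted cells and 0.870 in CK5-traced controls. Among the sorted libraries alone, CK5-traced control replicate 1 correlated most with CK5-traced AR-deleted replicate 2 (r = 0.941), and CK5-traced control replicate 2 with CK5-traced AR-deleted replicate 1 (r = 0.847). Genes are not independent replicates, so these values only describe the agreement of libraries.

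Ar, the targeted gene (ENSMUSG00000046532, chromosome X, 98148769 to 98323215 on the plus strand in GRCm38), was measured in every library first. Its value was 8.42 in the CK8-traced control and 8.08 and 8.38 in the CK5-traced controls. It was 8.80, 7.85 and 8.50 in the CK8-traced AR-deleted libraries, and 7.47 and 7.39 in the CK5-traced AR-deleted libraries. AR-deleted cells averaged 8.00 ± 0.63 (SD, n = 5) and controls 8.29 ± 0.18 (SD, n = 3). The difference of -0.29 gave p = 0.464 in a two-sided exact permutation test, whose smallest possible p is 0.0179. Both CK5-traced AR-deleted libraries lay below both CK5-traced controls, whereas the CK8-traced AR-deleted libraries lay on both sides of their control. Bulk tissue was at 9.67 ± 0.22 (SD, n = 6). The deposited value is a gene total that still counts exons outside the deleted part, so it does not check the genotype labels.

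The comparison of AR-deleted with control luminal cells over both lineages asks what the receptor does for gene expression in these cells. Of the genes ranked first, Stat5a, a transcription factor of cytokine and hormone signalling, was at 7.64 ± 0.72 (SD, n = 5) in AR-deleted and 10.14 ± 0.07 (SD, n = 3) in control cells. Tmprss11g, a transmembrane serine protease gene, was below the floor in all 3 controls and in bulk tissue and at 6.47 ± 1.24 (SD) in AR-deleted cells, where all 5 libraries lay above the floor. Ephx4, an epoxide hydrolase family gene, likewise was below the floor in the 3 controls and at 5.90 ± 1.18 (SD) in AR-deleted cells. Car12, which encodes a carbonic anhydrase, was at 10.40 ± 0.82 (SD) against 8.13 ± 0.92 (SD). Echdc2 and Dnase1l2 were at 10.98 and 8.52 in AR-deleted and at 11.86 and 9.83 in control cells. None of these 6 genes passed the threshold, although the 5 libraries did not overlap the 3 in any of them: the adjusted p was 0.812 for Tmprss11g (log2 difference 7.53, SE 1.24), 0.925 for Stat5a (-2.50, SE 0.45) and 1.00 for the others. Limma found 0 of 13400 genes past the threshold in either direction. At an unadjusted p under 0.05 there were 544 genes (428 higher, 116 lower), against 670 expected by chance. Values of 329 genes did not overlap between the groups, or 2.46%, where chance gives 3.57%.

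**Figure D1:**
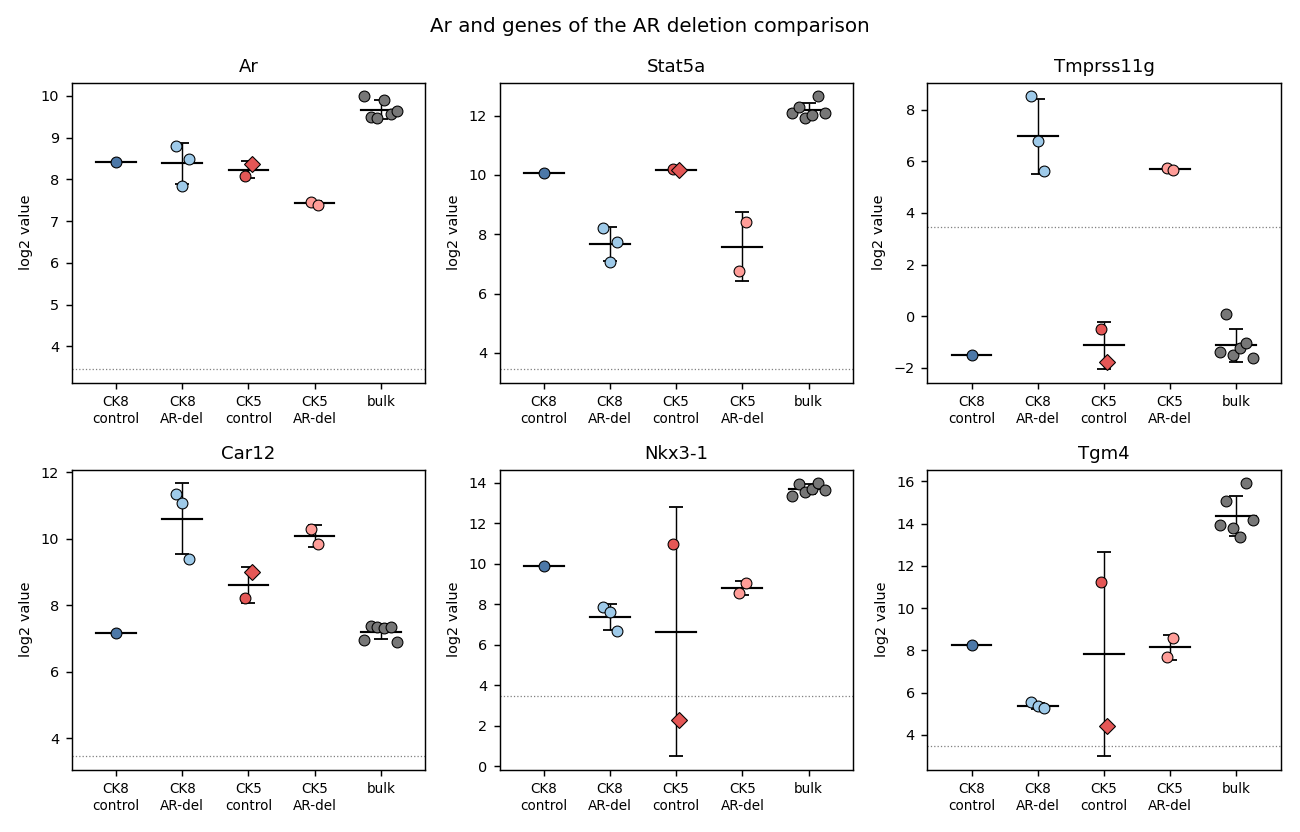
Log2 values of Ar, Stat5a, Tmprss11g, Car12, Nkx3-1 and Tgm4 in every library (points), with group means (lines) and SD (bars, where n is at least 2); the diamond is CK5-traced control replicate 2 and the dotted line the floor of 3.46. Stat5a is at 10.06 to 10.19 in the 3 controls and at 6.77 to 8.41 in the 5 AR-deleted libraries, while Nkx3-1 and Tgm4 are at 2.30 and 4.41 in CK5-traced control replicate 2 and higher in the other 2 controls.

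Among gene lists, 4 of 31 passed camera in the main AR comparison. The leukocyte list was higher in AR-deleted cells (14 of 14 members, median log2 difference 1.19, adjusted p = 0.00474), with Cd74 at 1.40 (SE 0.44) and the complement gene C1qb at 2.51 (SE 1.22). The neuroendocrine list was also higher (6 of 6 members, median 2.61, adjusted p = 0.00494). Its member Scg2, a secretogranin, was below the floor in the 3 controls and averaged 2.96 ± 3.85 (SD, n = 5) in AR-deleted cells. Lower lists were prostate secretory proteins (14 of 19 members, median -0.86, adjusted p = 0.0389) and immediate early genes (13 of 18, median -0.32, adjusted p = 0.0250). Secretory members with the smallest p were Timp4 (-0.72, SE 0.36), Rnase1 (-1.30, SE 0.66), Acpp, a secreted acid phosphatase (-1.33, SE 0.69), and Mme (-1.23, SE 0.71). With single libraries left out, Timp4 ran from -1.03 to -0.29, Rnase1 from -1.96 to -0.64, Acpp from -1.74 to -0.68 and Mme from -2.05 to -0.58. Immediate early members were Ier3 (-0.56, SE 0.27), Hspa1a (-1.07, SE 0.58), Hspa1b (-0.92, SE 0.57) and Zfp36 (-0.36, SE 0.34). That list, called immediate early for short, also holds stress genes such as the heat shock genes Hspa1a and Hspa1b. As single libraries were left out, Ier3 ran from -0.70 to -0.20 and Hspa1a from -1.81 to -0.28. Hspa1b ran from -1.74 to -0.15 and Zfp36 from -0.86 to -0.01. No single member of these 4 lists passed, over all genes or adjusted over the list alone. With an estimated correlation the p values, in the order leukocyte, neuroendocrine, immediate early and secretory, were 0.154, 0.0969, 0.331 and 0.335 before adjustment (adjusted p = 0.761 for each), and fry called 0 lists. Each of the 4 calls was lost when some single library was left out. The secretory list no longer passed without the CK8-traced control (adjusted p = 0.921, median 0.11), CK5-traced control replicate 1 (0.666, median 0.10), or CK8-traced AR-deleted replicate 2 (0.158) or 3 (0.141). The leukocyte list did not pass without CK5-traced control replicate 2 (0.0898) or CK5-traced AR-deleted replicate 2 (0.0561), nor did the neuroendocrine list without CK5-traced control replicate 2 (0.0552). Immediate early genes did not pass without CK5-traced control replicate 2 (0.817), CK5-traced AR-deleted replicate 1 (0.140) or 2 (0.361), or CK8-traced AR-deleted replicate 1 (0.0609). The androgen response list did not pass (24 of 41 members lower, median -0.09, adjusted p = 0.451).

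Leaving out CK5-traced control replicate 2 raised the number of lists most. In that library the androgen-induced homeobox gene Nkx3-1 was at 2.30, against 10.99 in the other CK5-traced control and 9.87 in the CK8-traced control. Fkbp5, a co-chaperone gene induced by androgen and glucocorticoid, was at 4.88 against 9.22 and 8.75, and the secretory transglutaminase Tgm4 at 4.41 against 11.24 and 8.24. These 3 genes were chosen after their values were seen. Without this library 0 genes passed (720 at an unadjusted p under 0.05). Then 9 lists passed camera, 7 lower and 2 higher, with 1 of the 4 above among them. Prostate secretory proteins were lower in 17 of 19 members (median -1.85, adjusted p = 3.44e-07) and the androgen response list in 31 of 41 (median -0.29, adjusted p = 0.00899; adjusted p = 0.495 with an estimated correlation for both). Without another control instead, both medians had the opposite sign and neither list passed: without CK5-traced control replicate 1 the secretory median was 0.10 and the androgen response median 0.06 (adjusted p = 0.666 and 0.922), and without the CK8-traced control 0.11 and 0.26 (adjusted p = 0.921 and 0.936). In the fit without CK5-traced control replicate 2 the log2 difference was -2.36 (SE 0.42, adjusted p = 0.287) for Nkx3-1, -2.97 (SE 0.51, adjusted p = 0.247) for Tgm4 and -1.71 (SE 0.47, adjusted p = 0.639) for Fkbp5.

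**Figure D2:**
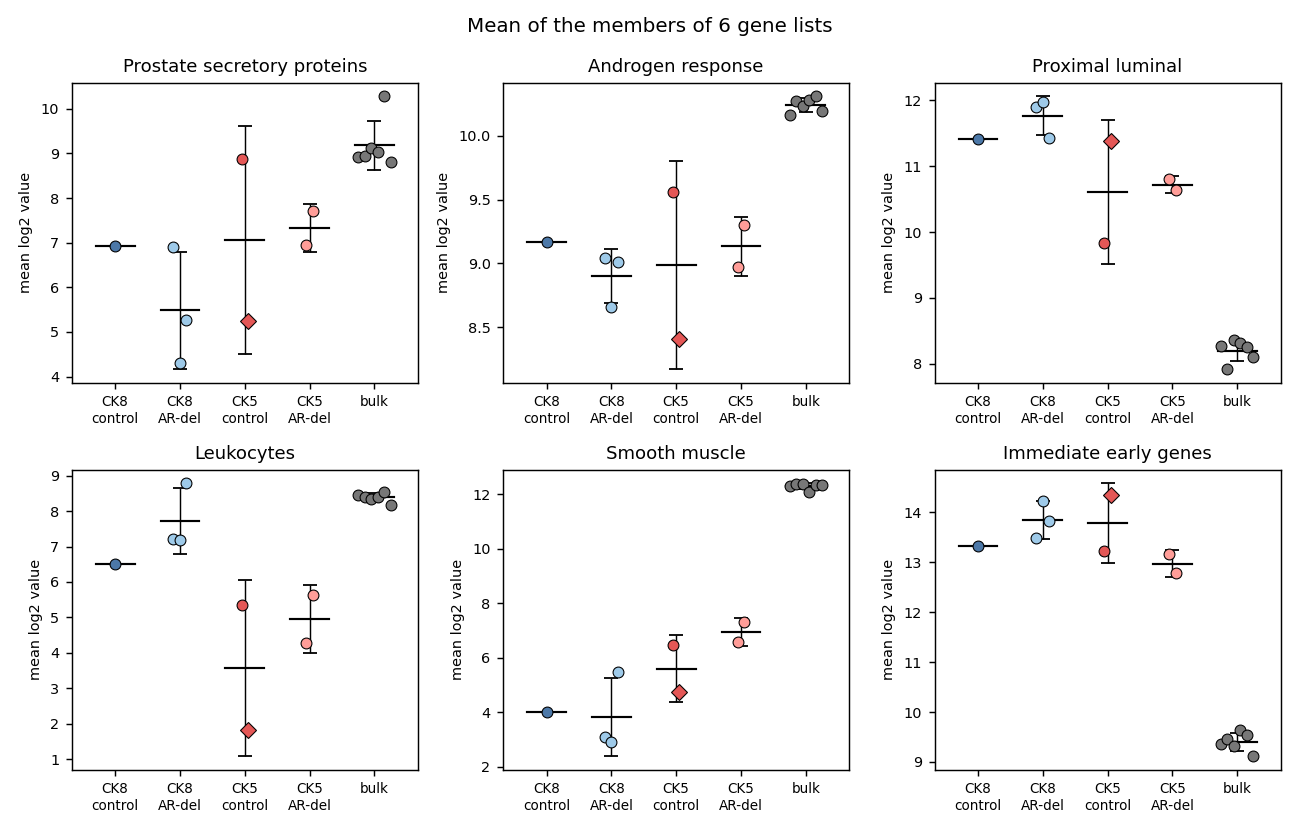
Mean log2 value over the members of 6 gene lists in every library (points), with group means (lines) and SD (bars, where n is at least 2); the diamond is CK5-traced control replicate 2. The leukocyte mean is 6.51 to 8.78 in the 4 CK8-traced and 1.81 to 5.63 in the 4 CK5-traced libraries, and CK5-traced control replicate 2 lies at 5.25 for secretory proteins against 8.87 in the other CK5-traced control.

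Within the CK5 lineage, AR-deleted cells were set against controls with 2 libraries each. The neural genes Serpini1 and Chl1 and Tmprss11g ranked first among the higher genes. Serpini1, a neuronal serpin, was at 6.09 ± 0.23 (SD, n = 2) and below the floor in both controls. Chl1, a neural cell adhesion gene, was at 6.14 ± 0.01 (SD, n = 2) and also below the floor in both controls. Tmprss11g was at 5.70 ± 0.06 (SD, n = 2) and below the floor in both controls. The CK8-traced control, by contrast, held Serpini1 at 5.60 and Chl1 at 5.52, above the floor. In CK8-traced AR-deleted libraries Serpini1 ran from 2.70 to 5.50 and Chl1 from 5.67 to 7.43. Among lower genes, Stat5a differed by -2.58 (SE 0.62), Rasd1, a hormone-responsive Ras-like gene, by -1.52 (SE 0.38) and Hist1h1c by -1.37 (SE 0.37). None passed (limma adjusted p of 1.00 for each): the fit called 0 of 13400 genes, with 181 at an unadjusted p under 0.05 against 670 expected. Of 31 lists, 4 passed camera. Immediate early genes were lower (16 of 18, median -0.97, adjusted p = 9.21e-11), including Hspa1b at -1.74 (SE 0.69) and Btg2 at -1.03 (SE 0.44). The neuroendocrine list (6 of 6, median 2.58, adjusted p = 0.00763), the leukocyte list (13 of 14, median 1.19, adjusted p = 0.00816) and the basal epithelial list (18 of 21, median 0.59, adjusted p = 0.00843) were higher. Scg2 was at 6.39 ± 1.26 (SD, n = 2) and below the floor in both controls, and the basal desmocollin gene Dsc3 differed by 1.29 (SE 0.63). Fry called 1 list, the 3 tested nerve and Schwann cell genes (adjusted p = 0.00149), and the adjusted p with an estimated correlation was 0.945 for each of the 4 lists. Without CK5-traced control replicate 2, 14 lists passed and 1 of these 4, immediate early genes, was among them; without CK5-traced AR-deleted replicate 1 or CK5-traced control replicate 1, 7 passed. Of the 4, only immediate early genes passed whichever CK5-traced library was left out, but without CK5-traced control replicate 2 their median was -0.47 (adjusted p = 0.00714) and Hspa1b differed by -0.52. The basal, leukocyte and neuroendocrine lists did not pass without CK5-traced control replicate 2 (adjusted p = 0.288, 0.981 and 0.222), nor the basal and leukocyte lists without CK5-traced AR-deleted replicate 2 (0.150 and 0.365).

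Within the CK8 lineage, 3 AR-deleted libraries were set against the single control, so no spread between controls was measured. 10 genes passed, all higher in AR-deleted cells: Kcns3, Zbtb25, Zfp90, Sh3bp5, Tm4sf4, Xrcc6bp1, Thumpd2, Rps6ka6, Scrn2 and Tmem184c. Kcns3, a modifier subunit of potassium channels, was at 8.44 ± 0.33 (SD, n = 3; adjusted p = 0.0223), and Tm4sf4, a tetraspanin-related membrane protein gene, at 9.15 ± 1.06 (SD, n = 3; adjusted p = 0.0261). All 10 lay below the floor in the CK8-traced control and above it in each of the other 7 sorted libraries, the 2 CK5-traced controls included. Lower genes with the smallest p were Akap12, a kinase-anchoring scaffold, at 4.06 ± 1.62 (SD, n = 3) against 9.94 (adjusted p = 0.0927), the actin cross-linker Flna at 9.85 ± 0.13 against 11.45 (adjusted p = 0.165), and Tmem144, below the floor against 6.57 (adjusted p = 0.182). They did not pass. At an unadjusted p under 0.05 there were 943 genes (748 higher, 195 lower). Leaving out each AR-deleted library in turn left 0 to 1 genes past the threshold, and quantile normalization and a pseudocount of 5 left 0. A filter at 50 gave 38 genes, robust moderation 41, no trend 50, sample weights 75 and all 14 libraries in the fit 915.

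Of 31 lists in the CK8 lineage, 3 passed camera, all lower in AR-deleted cells. Basal epithelial genes were lower in 19 of 21 members (median -1.34, adjusted p = 0.000451), including the integrin gene Itgb4 (-1.52, SE 0.52), Cav1 (-2.63, SE 1.02) and Snai2 (-1.93, SE 0.80). Secretory proteins were lower in 15 of 19 (median -1.30, adjusted p = 0.00557), including Timp4 (-1.28, SE 0.53) and Acpp (-2.20, SE 1.00). Cell cycle genes were lower in 22 of 32 (median -0.56, adjusted p = 0.00557), including Ccnb2 (-1.85, SE 0.58) and Ube2c (-1.46, SE 0.52). The only members to pass, adjusted over the list alone, went the other way: Dsc3 of the basal list (4.30) and the replication licensing gene Cdc6 (5.33), both below the floor in the control. Estimating the correlation gave an adjusted p of 0.800 for all 3 lists. Without AR-deleted replicate 3 only 1 list passed, and without replicate 1 there were 5. Basal genes passed whichever AR-deleted library was left out. The secretory list did not pass without replicate 2 (adjusted p = 0.0738) or 3 (0.0742), nor the cell cycle list without replicate 1 (0.0713) or 3 (0.0801).

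The interaction asks whether the AR effect differed between the lineages. Limma found 0 of 13400 genes, with 618 at an unadjusted p under 0.05 (134 higher, 484 lower). The smallest p belonged to Zbtb25 (-7.92, SE 1.22), Kcns3 (-6.90, SE 1.16) and Egr2 (-4.40, SE 0.75) on the lower side, each with adjusted p = 0.342, and the protocadherins Pcdhb14 (12.68, SE 3.08) and Pcdhga1 (12.92, SE 3.16) and Akap12 (5.91, SE 1.54) on the higher side. Pcdhga1 overlaps other genes of its cluster, so its value is uncertain. Pcdhb14 and Pcdhga1 were at 6.80 and 6.30 in the single CK8-traced control. Both were below the floor in CK8-traced AR-deleted and CK5-traced control libraries. In CK5-traced AR-deleted libraries Pcdhb14 was at 4.37 and 4.25, and Pcdhga1 at 4.75 and 3.70. The size of these differences thus rests on values below the floor and on 1 control. Zbtb25 and Kcns3 were below the floor in that control. By camera 5 of 31 lists differed between the lineages. The AR effect on basal genes was higher in the CK5 than in the CK8 lineage (19 of 21 members, median difference 1.78, adjusted p = 3.51e-06), as were those on cell cycle (23 of 32, 0.67, adjusted p = 0.0315), secretory (16 of 19, 1.71, adjusted p = 0.0371) and cholesterol synthesis genes (19 of 22, 0.38, adjusted p = 0.0371). That on immediate early genes was lower (15 of 18, -1.69, adjusted p = 2.40e-06). Snai2 (2.86, SE 1.06), Ccnb2 (1.92, SE 0.77), Wfdc15b (1.81, SE 1.24), Hmgcr (1.58, SE 0.78) and Fos (-2.43, SE 0.86) were among their members. With an estimated correlation the adjusted p was 0.917 for each, and 2 to 8 lists passed when libraries were left out: 2 without CK5-traced AR-deleted replicate 2, 3 without CK8-traced AR-deleted replicate 3 and 8 without CK5-traced control replicate 1. Basal and immediate early genes passed in each of these fits. The other 3 lists each failed in 4 of them, with an adjusted p of up to 0.940 for secretory genes (without CK5-traced control replicate 2), and 0.829 for cell cycle and 0.775 for cholesterol synthesis genes (both without CK5-traced AR-deleted replicate 2).

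The lineage comparison asks whether luminal cells descended from CK5-expressing cells differ from those descended from CK8-expressing cells, with genotype as a term. Genes of urothelium and of proximal luminal epithelium were lower in CK5-traced cells. Upk1b, a urothelial plaque protein (ENSMUSG00000049436, chromosome 16, 38773184 to 38800328), was at 10.34 ± 0.71 (SD, n = 4) in CK5-traced and 12.69 ± 0.28 (SD, n = 4) in CK8-traced cells, a model difference of -2.46 (SE 0.32, adjusted p = 0.0415). Ppp1r1b, a phosphatase regulator and proximal luminal marker (ENSMUSG00000061718, chromosome 11, 98348404 to 98357796), was at 10.06 ± 0.42 against 11.87 ± 0.31 (SD, n = 4 each; -1.91, SE 0.26, adjusted p = 0.0415). Naip5, an inflammasome sensor of bacterial flagellin (ENSMUSG00000071203, chromosome 13, 100211739 to 100246323), was at 8.75 ± 0.33 against 11.11 ± 0.31 (SD, n = 4 each; -2.38, SE 0.28, adjusted p = 0.0335). Naip5 belongs to a cluster of near-identical copies, so its value is uncertain. The 4 libraries of each lineage did not overlap for these 3 genes, the only ones of 13400 past the threshold in limma (1009 at an unadjusted p under 0.05, 670 expected). Cxcl10, an interferon-induced chemokine, was at 11.96 ± 0.69 against 9.84 ± 0.52, Fmo6 at 12.02 ± 0.79 against 10.23 ± 0.92, and Upp1, a uridine phosphorylase gene, at 8.70 ± 0.97 against 6.08 ± 1.86 (SD, n = 4 each). They ranked first among genes higher in CK5-traced cells and did not pass (adjusted p = 0.240 each). Overall 627 genes had no overlap (4.68%, where chance gives 2.86%). Without CK5-traced control replicate 2, 9 genes passed, the 3 among them. Without CK8-traced AR-deleted replicate 3 these were Naip5, Wfdc2 and Fmo6, while Upk1b and Ppp1r1b did not pass (adjusted p = 0.056 and 0.0766), and without any other sorted library there were 0. The 3 calls were also lost without limma's trend, where 5 other genes passed, all higher (adjusted p = 0.252 for Upk1b, 0.231 for Ppp1r1b and 0.129 for Naip5). In the mean of the genotype strata the adjusted p was 0.125 for each, and quantile normalization lost Ppp1r1b (0.0773).

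**Figure D3:**
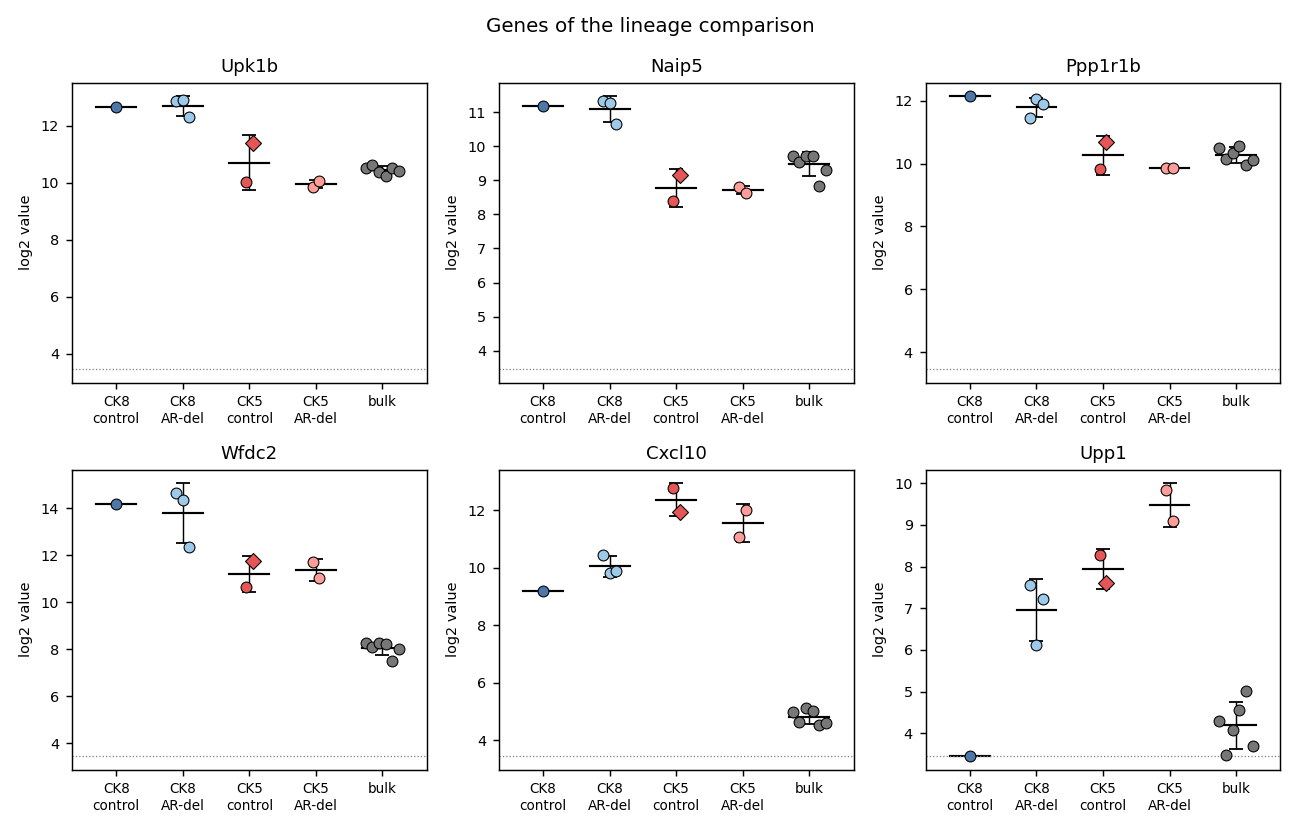
Log2 values of Upk1b, Naip5, Ppp1r1b, Wfdc2, Cxcl10 and Upp1 in every library (points), with group means (lines) and SD (bars, where n is at least 2); the diamond is CK5-traced control replicate 2 and the dotted line the floor of 3.46. Upk1b, Naip5 and Ppp1r1b are lower in all 4 CK5-traced than in all 4 CK8-traced libraries, with means of 10.34, 8.75 and 10.06 against 12.69, 11.11 and 11.87.

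Among lists, 17 of 31 passed camera in the lineage comparison. Proximal luminal genes were lower in CK5-traced cells (14 of 18, median -0.78, adjusted p = 1.09e-07), with Wfdc2 at -2.62 (SE 0.48), Gsta4 at -1.88 (SE 0.36) and Krt4 at -1.98 (SE 0.51); 6 members passed adjusted over the list alone and 1 over all genes. Urothelial genes were lower (5 of 8, median -0.66, adjusted p = 0.000877), with Upk1a at -2.28 (SE 0.54) and Upk2 at -2.80 (SE 1.01). Luminal identity genes followed (14 of 18, median -0.22, adjusted p = 0.00544), among them the protease gene Tmprss2 (-1.33, SE 0.33). Leukocyte markers (13 of 14, median -2.82, adjusted p = 1.40e-10), interferon-stimulated genes (16 of 17, -1.24, adjusted p = 7.39e-09) and antigen presentation genes (9 of 10, -1.22, adjusted p = 4.45e-07) were also lower, with Lyz2 at -5.70 (SE 1.56), Psmb8 at -1.43 (SE 0.37) and H2-Aa at -2.73 (SE 0.62). Adjusted over the list alone, 8, 5 and 6 of their members passed, against 0 over all genes. Immediate early (13 of 18, -0.19, adjusted p = 0.0351) and respiratory chain genes (22 of 25, -0.15, adjusted p = 0.0480) were lower by less.

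Stromal marker lists were higher in CK5-traced cells, but their means overlapped between the lineages and lay far below those of bulk tissue. The fibroblast mean was 4.58 in CK5-traced control replicate 2, against 4.74 and 5.38 in CK8-traced AR-deleted replicates 2 and 3. The smooth muscle mean was 4.75 there, against 5.47 in CK8-traced AR-deleted replicate 3. Col6a3, named below, was under the floor in every CK8-traced library. Fibroblast genes (15 of 16, median 2.48, adjusted p = 6.54e-08) and smooth muscle genes (11 of 11, 3.53, adjusted p = 8.27e-07) passed, with the collagen gene Col6a3 at 5.76 (SE 1.19) and the smooth muscle actin gene Acta2 at 3.53 (SE 0.77). Glucocorticoid response (11 of 12, 0.41, adjusted p = 0.00206), p53 target (14 of 18, 0.57, adjusted p = 0.00232), Hedgehog, FGF and BMP (13 of 15, 0.68, adjusted p = 0.00249) and basal genes (18 of 21, 0.30, adjusted p = 0.00519) were higher too. So were cell cycle (25 of 32, 0.31, adjusted p = 0.0146), neuroendocrine (6 of 6, 2.35, adjusted p = 0.0191) and endoplasmic reticulum folding genes (18 of 27, 0.11, adjusted p = 0.0405). Examples are the metallothionein gene Mt2 (1.17, SE 0.29), Trp53inp1 (1.10, SE 0.31), Spry1 (1.14, SE 0.32), Dsc3 (2.39, SE 0.62), Aurka (1.04, SE 0.45), Chga (3.75, SE 1.88) and Dnajb9 (1.58, SE 0.41). With an estimated correlation the adjusted p of the 17 lists was 0.0761 or above, that smallest value being for antigen presentation. When each of the 8 libraries was left out in turn, 10 of the 17 lists always passed and 7 did not. The basal list lost its call without CK8-traced AR-deleted replicate 1 (adjusted p = 0.237) or CK5-traced AR-deleted replicate 1 (0.0520) or 2 (0.159). Among control cells alone 17 of 21 basal genes were lower (median -0.66, adjusted p = 0.100). The highest adjusted p was 0.828 for cell cycle and 0.502 for immediate early genes (both without CK5-traced AR-deleted replicate 2), 0.0809 for neuroendocrine genes (without CK8-traced AR-deleted replicate 3) and 0.432 for endoplasmic reticulum folding genes (without CK5-traced control replicate 1). It was 0.767 for respiratory chain genes (without CK8-traced AR-deleted replicate 1) and 0.0643 for glucocorticoid response genes (without the CK8-traced control). Fry called 5 lists: interferon, antigen presentation and urothelial genes lower (adjusted p = 0.0260, 0.00400 and 0.0260), and smooth muscle and p53 targets higher (adjusted p = 0.0448 and 0.0260).

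Lineage was also compared within each genotype. Among AR-deleted cells (2 CK5-traced against 3 CK8-traced libraries), limma called 0 genes, with 774 at an unadjusted p under 0.05. Upk1b (-2.74, SE 0.40), Naip5 (-2.36, SE 0.37) and Ppp1r1b (-1.93, SE 0.34) ranked first on the lower side (adjusted p = 0.473, 0.473 and 0.760). On the higher side were Rnd3, an atypical Rho GTPase gene (1.60, SE 0.29), Tmem144 (6.65, SE 1.37) and Epgn, an EGF receptor ligand gene (3.10, SE 0.66). Without CK8-traced AR-deleted replicate 3, 4 genes passed. Of 31 lists 16 passed camera: basal genes were higher (20 of 21, median 1.25, adjusted p = 1.45e-07), and leukocyte (14 of 14 lower, -2.72, adjusted p = 1.45e-07) and proximal luminal genes (14 of 18 lower, -0.95, adjusted p = 1.24e-05) lower. Secretory genes were higher (14 of 19, median 1.09, adjusted p = 0.0454), with Sbp at 8.29 (SE 2.41) and Msmb at 7.55 (SE 2.46), while Pigr was at -2.61 (SE 0.49). This call was lost without CK8-traced AR-deleted replicate 2 (adjusted p = 0.243) or 3 (0.232) or CK5-traced AR-deleted replicate 2 (0.183). Sbp was at 7.94 and 15.11 in the 2 CK5-traced AR-deleted libraries, and its difference ran from 4.71 to 11.88 as libraries were left out. In all, 9 of the 16 lists passed in each such fit, basal, leukocyte and proximal luminal genes among them. The smallest adjusted p of the 16 lists with an estimated correlation was 0.218.

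Among controls, 2 CK5-traced libraries were set against 1 CK8-traced. Limma called 0 genes, with 827 at an unadjusted p under 0.05. Clca3, a secreted goblet-type protein gene, was at 7.79 ± 1.49 (SD, n = 2) against 14.10 (adjusted p = 0.0987), and the mucin gene Muc1 was below the floor in both CK5-traced controls against 7.86 (adjusted p = 0.190). Naip5 differed by -2.41 (SE 0.50, adjusted p = 0.151). Tmem184c, Thumpd2 and Zbtb25, the first on the higher side, are among the 10 genes below the floor in the CK8-traced control (adjusted p = 0.0829 each). Of 31 lists 8 passed camera. Leukocyte, proximal luminal, antigen presentation, interferon and urothelial genes were lower in CK5-traced cells (medians -3.34, -0.55, -1.12, -1.15 and -1.30). Fibroblast, glucocorticoid response and immediate early genes were higher (4.02, 0.67 and 0.73). The smallest adjusted p of these 8 lists with an estimated correlation was 0.495, and without CK5-traced control replicate 2 there were 13 lists. Without CK5-traced control replicate 1 the proximal luminal, urothelial, interferon and glucocorticoid response lists did not pass (adjusted p = 0.803, 0.367, 0.153 and 0.222), and without replicate 2 immediate early genes did not (0.701). The proximal luminal mean was 11.38 in CK5-traced control replicate 2 and 11.41 in the CK8-traced control, against 9.83 in CK5-traced control replicate 1.

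Control luminal cells were set against bulk prostate to describe what the sort holds. Among the genes with the largest rises in sorted cells were Sprr1a, Krt16 and Prr9 of stratified epithelium and the stress transcription factors Fosl1 and Atf3, and markers of stromal cells fell. Sprr1a, a cornified envelope precursor, was at 15.22 ± 0.36 (SD, n = 3) against 6.71 ± 0.58 (SD, n = 6; limma adjusted p = 1.08e-10). Krt16 was at 9.91 ± 1.12 against 0.72 ± 0.90 (adjusted p = 1.48e-06), Prr9 at 11.36 ± 0.09 against 1.49 ± 0.72 (adjusted p = 6.70e-08) and the EGF receptor ligand gene Epgn at 8.27 ± 0.93 against -0.08 ± 1.07 (adjusted p = 2.26e-06). Fosl1 and Atf3 were at 11.08 ± 0.44 and 16.20 ± 0.69 against 2.29 ± 1.44 and 7.92 ± 0.51 (SD, n = 3 and n = 6; adjusted p = 1.24e-07 and 3.14e-10). The smooth muscle myosin gene Myh11 was at 3.36 ± 2.72 against 15.12 ± 0.19 (adjusted p = 1.36e-06). Tnxb, Hhip, Mrvi1, Jph2 and Postn were below the floor in the 3 control luminal libraries and at 11.05, 10.47, 10.54, 10.05 and 11.18 in bulk tissue. The fit of all 14 libraries takes 1 spread per gene, although bulk replicates correlated more closely than sorted ones. Its p values can thus be too small. Of 14959 genes, 10629 passed, 3111 higher and 7518 lower. That split depended on scaling: with quantile normalization 5066 were higher and 5057 lower, and with median centring 5180 and 4883. The median log2 difference of all genes was -1.12 as deposited, -0.06 after quantile normalization and -0.12 after median centring. Camera sets each list against the other genes, that is, relative to this shift.

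Of 32 lists, 15 passed camera in the comparison with bulk tissue, 10 higher and 5 lower in luminal cells. Immediate early genes were higher in 17 of 18 members (median 4.21, adjusted p = 2.18e-13; 16 members passed), with Dusp1 at 5.98 (SE 0.19) and Ier3 at 5.76 (SE 0.19). Respiratory chain genes were higher in 25 of 25 (median 1.66, adjusted p = 6.33e-13), and proximal luminal genes in 16 of 18 (median 3.48, adjusted p = 1.57e-06), with Tacstd2 at 4.62 (SE 0.32) and Krt7 at 4.02 (SE 0.42). Cell cycle (24 of 32, 1.19, adjusted p = 1.23e-05), cholesterol synthesis (16 of 22, 0.91, adjusted p = 0.000216) and NF-kB inflammatory genes (16 of 18, 1.60, adjusted p = 0.000645) were higher, with Ccnb1 at 4.14 (SE 0.43), Idi1 at 2.83 (SE 0.22) and Cxcl2 at 7.34 (SE 0.71). MYC and ribosome biogenesis (15 of 22, 0.47), glutathione (11 of 18, 0.79), epithelial junction (13 of 24, 0.14) and p53 target genes (10 of 18, 0.50) were higher by less, with adjusted p = 0.00117, 0.00117, 0.0230 and 0.0344. Epcam was at 2.51 (SE 0.14), Gsto1 at 3.61 (SE 0.20) and Cdkn1a at 5.18 (SE 0.31).

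Lower lists were fibroblast (17 of 18 members, median -8.14, adjusted p = 0.00241), nerve and Schwann cell (10 of 10, -7.44, adjusted p = 0.00286), endothelial (12 of 12, -7.80, adjusted p = 0.00408), smooth muscle (12 of 12, -7.63, adjusted p = 0.00786) and Notch pathway genes (15 of 16, -3.75, adjusted p = 0.0371). Their members include Dpt (-11.16, SE 0.62), Sox10 (-8.96, SE 0.73), Cdh5 (-9.91, SE 0.65), Mylk (-6.75, SE 0.59) and Notch1 (-2.96, SE 0.22). Notch pathway genes did not pass without CK5-traced control replicate 1 (adjusted p = 0.0570), nor the higher p53 target genes without CK5-traced control replicate 1 (0.0522) or 2 (0.0585); the other 13 lists passed in each fit with 1 library left out. Androgen response genes did not pass camera (31 of 42 lower, median -1.16, adjusted p = 0.832), though 24 members were lower and 9 higher past the threshold over all genes. With an estimated correlation the adjusted p of the 15 lists was 0.0757 or above, the smallest being for glutathione genes; fry called 29 lists. The basal list mean was 8.14 to 10.10 in the sorted libraries and 9.42 ± 0.08 (SD, n = 6) in bulk tissue. Basal transcripts were thus not low in sorted cells as stromal ones were. RNA isolation, amplification, sorting, genotype, age and tamoxifen differ together in this comparison, so no difference in it can be assigned to cell type alone.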

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

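The tests of transcripts missed in a single control and of CK5-traced control replicate 2 were chosen only after those results were seen, as was the test of an AR effect present in both lineages.

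The AR effect differed between the lineages for 5 gene lists by camera's test of the interaction, which has a single CK8-traced control. The median difference, CK5 lineage minus CK8 lineage, was 1.78 for basal genes, 1.71 for prostate secretory genes, 0.67 for cell cycle genes, 0.38 for cholesterol synthesis genes and -1.69 for immediate early genes. Without CK5-traced control replicate 2 it fell to 0.09 for secretory and 0.13 for cholesterol synthesis genes, and without CK5-traced AR-deleted replicate 2 to 0.14 for cell cycle genes. Basal genes averaged 9.53 in the CK8-traced control and 8.43 ± 0.37 (SD, n = 3) in CK8-traced AR-deleted cells, against 9.11 ± 0.85 (SD, n = 2) and 9.94 ± 0.22 (SD, n = 2) in the CK5 lineage. Sorted libraries lay at 8.14 to 10.10 and bulk tissue at 9.42, so basal transcripts were present in all of them. The basal differences, here and in the other comparisons, can thus not be assigned to luminal cells alone. The share of basal cells was not tested. No list passed with an estimated correlation, where the p values were 0.0596 for basal, 0.344 for secretory, 0.383 for cell cycle, 0.349 for cholesterol synthesis and 0.116 for immediate early genes.

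CK5-traced control replicate 2 was low in the products of mature secretory cells. Its 19 tested secretory genes deviated by -2.75 log2 units on average from the mean of the other 2 control libraries, and its 41 androgen response genes by -0.95. Leukocyte and endoplasmic reticulum folding genes were also low (deviations -4.11 and -0.78), while immediate early and proximal luminal genes were high (1.07 and 0.76). Antigen presentation (-1.62), fatty acid synthesis (-1.35), basal (-1.11), cholesterol synthesis (-0.63) and respiratory chain genes (-0.36) were low too, and junction genes high (0.32). The library was thus not low in secretory genes alone. It also had the most genes (101) below the floor while at or above 5.67 in each of the other 7 sorted libraries. Loss of transcripts that strikes genes at random, as the only source of the secretory and androgen response deviations, was tested against random lists. Among 10000 random lists of the same size and expression, the secretory deviation lay at percentile 0 and the androgen response deviation at percentile 0.04 (permutation test over random lists, two-sided p = 0.00207 and 0.00620 adjusted over the 31 lists scored). Random lists hold unrelated genes, so a list whose members vary together can lie far out for other reasons. Leukocyte and immediate early genes lay as far out as secretory genes, at percentiles 0 and 100 (adjusted p = 0.00207 each in the same test). The test thus does not exclude lost transcripts in this library, nor does it argue against them. CK8-traced AR-deleted replicates 2 and 3 had secretory means of 4.29 and 5.26, against 5.25 in this library. A label exchanged with a CK5-traced AR-deleted library cannot be told apart: 0 of the 2 such libraries reached the secretory mean of CK5-traced control replicate 1 (8.87), but at 6.96 and 7.71 they lay above that of the CK8-traced control (6.93). Ar goes with the labels within the CK5 lineage, at 8.38 in this library and 8.08 in the other control against 7.47 and 7.39, but AR-deleted libraries of the CK8 lineage reached 8.80, so it does not exclude the exchange. Stat5a was at 10.15 in this library against 6.77 and 8.41, but it is named because it differs between the labels as given. More proximal luminal cells in this library cannot be told apart: the proximal luminal deviation lay at percentile 99.89, but the mean of 11.38 was no higher than in the CK8-traced control (11.41), where secretory genes, Tgm4 and Nkx3-1 were at 6.93, 8.24 and 9.87 against 5.25, 4.41 and 2.30. A single AR-deleted library under a control label cannot be told apart by Ar. At 8.38 in this library, Ar lay 0.947 above the mean of the CK5-traced AR-deleted libraries. It was still inside the range of all AR-deleted libraries, 7.39 to 8.80. Differences between litters stay open and untested.

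The 10 genes higher in CK8-traced AR-deleted cells rest on 1 control. All 10 of the 10 were below the floor in that library and above it in both CK5-traced controls, so transcripts missed in the single control library may account for them. That library had 68 genes below the floor that were at or above 5.67 in each of the other 7 sorted libraries. An effect of AR loss present in both lineages was tested by the CK5-traced libraries, where 4 of the 10 genes were higher in both AR-deleted libraries than in both controls. That number decides nothing, and with 1 control library an AR effect in the CK8 lineage cannot be told apart from missed transcripts.

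In bulk tissue 9 of 85 genes and list means had 1 pool far from the other 5, where chance gives such a gap in 1 of 20 (4.25 of 85). The items are not independent, since list means stand beside their own members, such as smooth muscle genes and Mylk or endothelial genes and Cdh5. The 9 can thus not be read as an excess over 4.25. The gap is given as a share of the whole range. Pool 4 was lowest in smooth muscle genes (0.718 of the range, 12.10 against 12.29 to 12.37), in Myh11 (0.630) and in Mylk (0.678), and highest in Epgn (0.807), which lay below the floor in all pools. Pool 1 was highest in endothelial genes (0.757, 8.38 against 8.08 to 8.16) and in Cdh5 (0.725), and lowest in MYC and ribosome biogenesis genes (0.673). Pool 2 was lowest in Nfkbia (0.676) and pool 5 in Il8 (0.677), the older symbol under which Cxcl15 was found. No biological explanation was tested.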

How the results depend on the processing

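The direction of the target gene held in all alternatives run, and Ar differed by -0.49 to -0.14 when single libraries were left out. Over all comparisons and alternatives, 132 gene and list counts stayed within 1.5 times the reported value and 60 did not. For single genes and lists, 5791 values kept their direction and side of the threshold, 255 no longer passed, 135 newly passed and 10 reversed. For a list, a reversal is a change in the direction of camera's test, which is relative to the other genes. Without limma's trend, the genes past the threshold were 3 (AR deletion), 5 (AR, CK5 lineage), 50 (AR, CK8 lineage), 4 (interaction), 5 (lineage) and 16 (lineage, AR-deleted cells); the 5 for lineage were all higher and none was among the 3 reported. With all 14 libraries in the fit they were 15, 10, 915, 478, 508 and 478, with 729 for lineage in controls. That fit takes its spread in part from the 6 bulk libraries, whose replicates correlated at 0.978 to 0.990 against 0.870 to 0.940 in sorted groups. It can thus set differences among sorted cells against too small a spread. For AR in the CK8 lineage, a pseudocount of 5 gave 0, quantile normalization 0, a filter at 50 gave 38, robust moderation 41 and sample weights 75. Sample weights gave 18 for lineage, 3 for lineage in AR-deleted cells and 14 for lineage in controls, where robust moderation gave 10; the mean of the 2 genotype strata gave 0 for lineage. The cause was not tested. Gene lists past the threshold with an estimated inter-gene correlation were 0 in each of the 8 comparisons. With fry they were 0 (AR deletion), 1 (AR, CK5 lineage), 0 (AR, CK8 lineage), 0 (interaction), 5 (lineage), 1 (lineage, AR-deleted cells), 0 (lineage, controls) and 29 (bulk tissue). Leaving out each library in turn gave 0 to 0 genes for AR deletion, 0 to 0 for AR in the CK5 lineage, 0 to 1 for AR in the CK8 lineage, 0 to 0 for the interaction, 0 to 9 for lineage, 0 to 4 for lineage in AR-deleted cells, 0 to 0 for lineage in controls and 10070 to 10323 for bulk tissue. The ranges for gene lists were 3 to 9, 3 to 14, 1 to 5, 2 to 8, 13 to 17, 13 to 19, 8 to 13 and 14 to 17 in the same order. Where this leaves a group with 1 library, that library is assumed to vary like the other groups; leaving out the CK8-traced control was possible only where other controls remain. Reversals came only in such fits. Without CK5-traced control replicate 2 these were immediate early genes in AR deletion (adjusted p = 0.817; range 1.05e-10 to 0.817) and in lineage among controls (0.701; 0.000273 to 0.701), leukocyte genes in AR in the CK5 lineage (0.981; 4.88e-06 to 0.981), and Jag2 (-0.21 to 6.53), Scg5 (-0.83 to 6.24) and the interaction of Tgm4 (-0.25 to 6.58). In lineage, cell cycle genes reversed without CK5-traced AR-deleted replicate 2 (adjusted p = 0.828; 5.35e-05 to 0.828), Bmp4 without the CK8-traced control (-0.12 to 3.22) and Ndufb10 without CK8-traced AR-deleted replicate 1 (-0.482 to 0.0205). Upk1a in lineage among controls reversed without CK5-traced control replicate 1 (-2.38 to 0.0247). The median of a list changed sign in 8 fits with 1 library left out, in 6 of them with camera's direction kept. In AR deletion this was so for secretory genes without the CK8-traced control (0.11) or CK5-traced control replicate 1 (0.10) and immediate early genes without CK5-traced control replicate 2 (0.04). In AR in the CK5 lineage it was so for leukocyte (-0.33) and neuroendocrine genes (-0.03) without that library. In lineage it was so for respiratory chain genes without CK8-traced AR-deleted replicate 1 (0.03), and immediate early genes without CK8-traced (0.03) or CK5-traced AR-deleted replicate 2 (0.02). These genes and lists then rest on fewer libraries. Depth is unknown, so how far it limits low genes cannot be given, and edgeR and DESeq2 were not run because the values are not counts.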

Other observations

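The tests of stromal dilution and of a single library were chosen only after the lineage result was seen; the other tests here were planned. All genes named in the next paragraphs were chosen after their values were seen, unless the comparisons above name them.

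Stat5b, the neighbour and paralog of Stat5a, was also lower in each of the 5 AR-deleted than in each of the 3 control libraries (7.12 ± 0.38 against 8.74 ± 0.47, SD; limma log2 difference -1.49, SE 0.45, adjusted p = 1.00). Skint8, a butyrophilin-like gene of epithelia, was below the floor in the 3 controls and in bulk tissue and at 4.30 ± 0.47 (SD, n = 5) in AR-deleted cells (adjusted p = 1.00). The basal keratin gene Krt14 was at 9.25 to 13.59 in the sorted luminal cells against 9.92 ± 0.07 (SD, n = 6) in bulk tissue, and lowest in CK8-traced AR-deleted replicate 1. The luminal keratin gene Krt8 was at 15.31 to 16.49 against 12.39 ± 0.09 (SD, n = 6).

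Seminal vesicle products differed widely between the bulk pools. The mean of 5 seminal vesicle genes ran from 0.81 in pool 2 to 11.39 in pool 5, and from -1.68 to -0.46 in sorted cells. Svs2 ran from 1.72 to 12.38, Svs4 from 2.06 to 13.32, Svs5 from 0.07 to 11.45 and Pate4 from 1.93 to 13.93, each lowest in pool 2 and highest in pool 5. Clu, the clusterin gene, was also lowest in pool 2 (11.54) and highest in pool 5 (15.63), as was Pax2 (-1.64 and 6.61), whereas Krt8 stayed between 12.28 and 12.47. The mean of 2 red blood cell genes was 7.86 to 8.48 in bulk tissue and 0.14 to 4.55 in sorted cells.

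Proximal luminal genes were lower in CK5-traced cells, and 3 technical explanations were tested. The sort for a reporter activated by keratin-driven Cre should remove stromal cells and leukocytes; how many remained is not known. Dilution of epithelial transcripts by stromal cells in the CK5-traced libraries, a candidate because fibroblast and smooth muscle genes were higher there, would lower epithelial junction genes as far. Their median difference was -0.04, or 0.738 above that of the proximal genes (95% bootstrap interval over members 0.148 to 1.45), which argues against it. Leukocytes in the CK8-traced libraries cannot be told apart from lineage by a covariate. In a fit with the leukocyte mean as a covariate the proximal median was -2.18 (interval -3.27 to -1.39) against -0.78 without it. But that mean was 6.51 to 8.78 in the CK8-traced and 1.81 to 5.63 in the CK5-traced libraries, so the covariate separates the lineages like the lineage term, and the bound planned for this test cannot decide. The intervals cover members and not libraries. Per-library means argue against leukocyte transcripts as the source of the proximal ones. Bulk tissue, though prepared differently, had leukocyte means of 8.18 to 8.55 but proximal means of 7.92 to 8.36. In CK8-traced libraries the proximal means were 11.41, 11.90, 11.96 and 11.42 at leukocyte means of 6.51, 7.21, 7.17 and 8.78. In CK5-traced libraries they were 9.83, 11.38, 10.81 and 10.63 at 5.34, 1.81, 4.27 and 5.63. A single library as the source of camera's call is argued against, since the list passed in 8 of 8 fits with 1 library left out (highest adjusted p = 2.60e-05). These fits used the preset correlation, and no lineage list passed with an estimated one. They show only that the call did not hang on 1 library. A difference in the regions from which the traced cells came may account for the pattern and was not tested, and other groupings of the libraries, given next, do not exclude chance.

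The AR deletion counts were no larger than those of other groupings. Of the 56 ways to set 5 sorted libraries against 3, 28 gave at least the 544 genes at an unadjusted p under 0.05 (highest other 1980), 46 gave at least 4 lists (highest other 13), and 38 gave at least 329 genes without overlap (highest other 1201). Chance could not be excluded for any of them. The groupings were not made within lineage, and the fits keep lineage as a term. The 1980 genes thus come from CK8-traced AR-deleted replicate 1 against the other 3 CK8-traced libraries. In the same way, 224 genes past the threshold come from CK5-traced control replicate 2 against the other 3 CK5-traced libraries.

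For lineage, 4 of the 35 groupings of 4 against 4 gave at least 3 genes (highest other 49), 2 gave at least 17 lists (highest other 20), and 5 gave at least 627 genes without overlap (highest other 1018). Chance could not be excluded for any of these. The 49 genes came from grouping the 3 controls with CK8-traced AR-deleted replicate 2. With genotype as a term this sets that library against the other 4 AR-deleted libraries. For bulk tissue, 1 of 84 groupings, the real one, gave 10629 genes (highest other 2). Every other grouping mixes sorted with bulk libraries in a group, which widens the spread. The low counts there thus follow from the design, and this test does not decide on chance. For the lists chance could not be excluded, since 27 groupings gave at least 15 (highest other 18).

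Effects were compared across the 13400 genes between strata, with 2 relations tested. Lineage differences in AR-deleted and in control cells correlated at r = 0.148 (rho = 0.0928). As high a correlation arose in 3 of 30 relabelings (permutation p = 0.100, adjusted p = 0.20, smallest possible p = 0.0333, highest other r = 0.302). AR effects in the CK5 and CK8 lineages correlated at r = 0.0537 (rho = 0.0231), with 7 of 24 relabelings as high (permutation p = 0.292, adjusted p = 0.292, smallest possible p = 0.0417, highest other r = 0.0877). Genes are not independent replicates, so only the relabelings give a p. A lineage effect shared by both genotypes and an AR effect shared by both lineages thus stay undecided.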
